A study of Mus musculus with 3 samples.

How the data were processed

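RNA was measured by polyA-selected, single-end sequencing of 50 nt on a DNBseq platform in 3 libraries of sorted B220+GFP+ pBIC2 lymphoma cells, per the labels. The deposited values are raw counts per gene, made by the authors with STAR 2.5.2b and featureCounts 1.6.0 on mm10 after FastQC, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. Each table listed 37646 genes, and no row named no gene. Coordinates, exon lengths and GC content were taken from GENCODE M21, to which 37536 gene identifiers matched without their version. Near-identical copies, such as Hspa1a and Hspa1b, the Bcl2a1 genes, the haemoglobin genes and related V segments, can share or lose reads, and their values are uncertain.

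The labels gave 1 group, and the libraries were numbered in accession order, which only names them. The comparison with germinal centre B cells was not analysed here, so no contrast between groups was fitted. Counts were normalised with TMM factors (0.969, 0.990 and 1.04) in edgeR 4.0.16 (R 4.3.3) after filterByExpr, and CPM are TMM-normalised throughout. Log2 CPM used a prior count of 2. The common biological coefficient of variation came from edgeR's dispersion estimate with an intercept only. DESeq2 1.42.0 was used for size factors as an alternative. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

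The depth was 15576975 to 17014022 counts, at which 3 counts correspond to 0.199, 0.184 and 0.169 CPM in tumours 1, 2 and 3. A count of 100 has an exact 95% Poisson interval of 81.4 to 122. Intervals cover counting error only.

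The gene lists below, the tests of the report and the choice of named genes were fixed before the data were examined. Further lists (12 T cell genes, 5 B-1 cell genes and 5 follicular B cell genes), the chromosome medians and the tests of explanations were added later. The lists were engineered loci, pan B cell, germinal centre, plasma cell, naive and memory B cell, ABC classifier, GCB classifier, classifier housekeeping, NF-κB targets, p53 targets, BCL2 family, proliferation, Myc and ribosome biogenesis, interferon response, MHC class II, MHC class I, checkpoint ligands, immediate early and heat shock, T cell, NK cell, macrophage and monocyte, neutrophil, erythroid, plasmacytoid dendritic cell, dendritic cell, stroma and endothelium, and sex-linked genes. Named were all engineered loci and classifier genes. Of each other list, the 3 members with the highest mean CPM were named, with every member under a mean of 1 CPM where 5 or fewer were, and the 3 members of largest SD for lists with high spread. Also named were the 10 most abundant genes outside mitochondrial, ribosomal protein and immunoglobulin genes, the 5 tumour-specific genes of largest distance per tumour and direction outside immunoglobulin, mitochondrial, predicted and ribosomal protein genes, and the most abundant V segments and heavy chain constant gene, with second segments from 10%. Some genes that this rule names are not reported here. Cd4, the shares of Ighg1, Ighg3 and Ighd, and light chain constant genes were added after their values were seen.

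The level of a list was the median over members of mean log2 CPM, as a percentile among 10000 random lists. The spread of a list was the median SD of log2 CPM between tumours over members with a mean of at least 1 CPM, among 10000 random lists matched in 20 bins of expression. A tumour-specific gene had at least 5 CPM in any tumour and lay at least 2 (log2) above or below both other tumours, which differed by less than 1. The ABC and GCB lists were compared by an exact permutation of labels over 15 genes (6435 regroupings).

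The steps were tested on simulated counts. For tumour-specific genes simulated with a coefficient of variation of 0.3, 25.4% of 67 genes changed 4-fold, 74.6% of 67 changed 8-fold and 86.4% of 66 changed 16-fold were recovered, and 4 of 9987 unchanged genes were called. The setting of 0.3 is below the common coefficient of 0.445 in these libraries, so false calls can be more frequent here than simulated. Simulated coefficients of 0.2, 0.4 and 0.6 were estimated as 0.198, 0.390 and 0.587. Of 1000 random lists, 5.6% reached the 95th percentile of spread and 6.5% that of level. Alternatives covered normalisation, filters, thresholds, prior count, gene length, denominators and leaving out each tumour.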

Results

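RNA sequencing was carried out on B cell lymphomas that arose in pBIC2 mice, a C57BL/6 model of the activated B cell type of diffuse large B cell lymphoma (ABC-DLBCL). In these mice, Cre recombinase expressed from the Cγ1 locus acts on floxed alleles of Trp53 (which encodes the tumour suppressor p53) and Prdm1 (which encodes Blimp1, a driver of plasma cell differentiation) and switches on a constitutively active IKK2 kinase, the activator of canonical NF-κB signalling. A human BCL2 transgene driven by the Eµ enhancer is also present. B220+GFP+ cells were sorted from the spleen, and 3 lymphoma libraries, named here tumours 1, 2 and 3, form 1 group. The totals were 15576975, 16477997 and 17014022 gene counts, and 19749, 20847 and 21844 genes had a count. The labels name germinal centre B cells as the control population, and that contrast was not analysed here. The values below are therefore levels in the lymphomas and their spread (SD, n = 3), with no test of a difference from normal B cells. The labels do not state that the libraries came from separate mice. Xist and Y-linked counts (given below) set tumour 1 apart from tumour 3 as female from male, and each tumour had other dominant V segments. The libraries are therefore not repeats of 1 clone. Each tumour has 1 library, so the spread between tumours may still be technical in part.

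The engineered genes differed widely in level. Ikbkb, the mouse gene of IKK2, was at 409 ± 65.2 CPM (TMM-normalised read counts scaled by library size; SD, n = 3), and Bcl2, the survival gene that the human transgene adds to, was at 183 ± 71.5 CPM. Trp53 was at 34.1 ± 10.6 CPM and Prdm1 at 8.39 ± 1.73 CPM. Ighg1, the constant gene at the Cγ1 locus that carries Cre, varied most, with 42.0 CPM in tumour 1, 99.7 CPM in tumour 2 and 6.14 CPM in tumour 3 (mean 49.3 CPM, and 23.9 CPM without tumour 2). In the mm10 assembly (GENCODE M21) the genes lie at chromosome 8, 22659212 to 22706589 (Ikbkb, ENSMUSG00000031537.15), chromosome 1, 106538178 to 106714274 (Bcl2, ENSMUSG00000057329.7), chromosome 11, 69580359 to 69591873 (Trp53, ENSMUSG00000059552.13), chromosome 10, 44437177 to 44528501 (Prdm1, ENSMUSG00000038151.13) and chromosome 12, 113325240 to 113330523 (Ighg1, ENSMUSG00000076614.7). A count over a whole gene cannot separate deleted from remaining exons, nor reads of a transgene from those of the endogenous gene, so these levels check neither the deletions nor the transgenes.

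**Figure D1:**
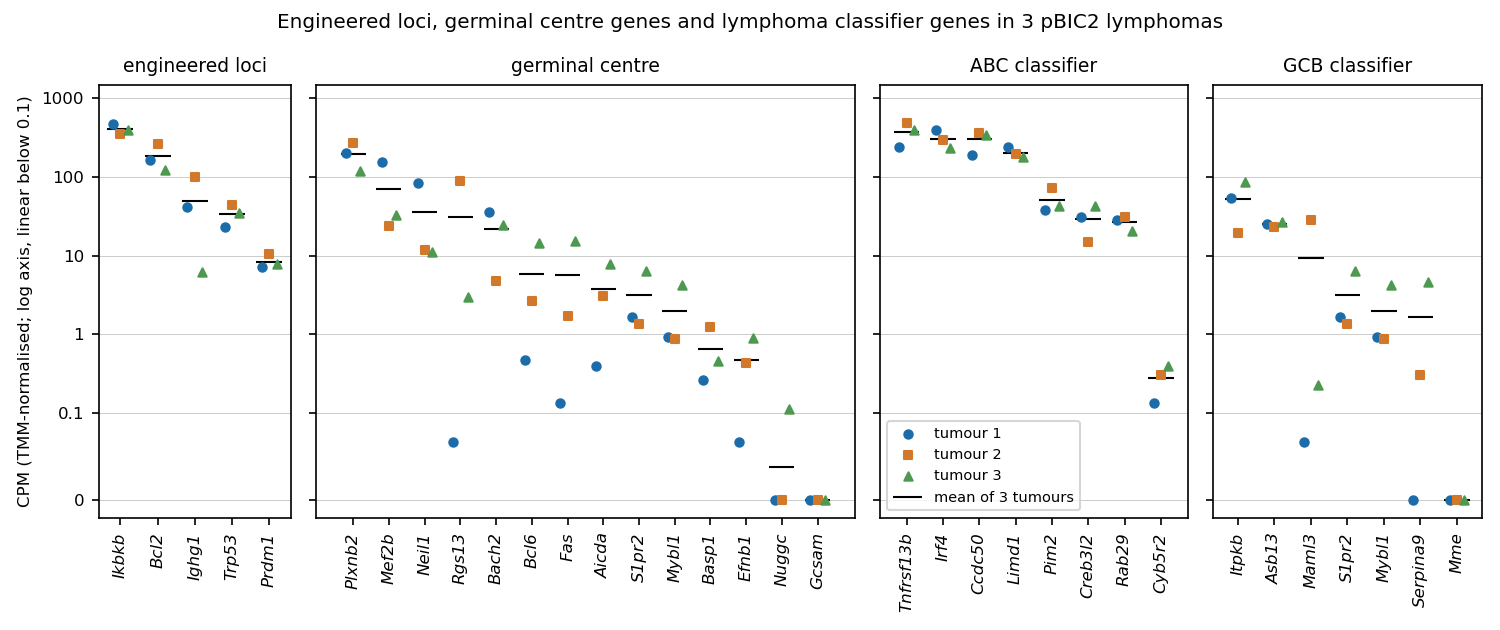
Level of each gene of 4 lists in CPM (TMM-normalised; log axis, linear below 0.1), with 1 symbol per tumour and a line at the mean of 3 tumours. Ikbkb sits near 409 CPM and Prdm1 near 8.39 CPM, and Gcsam and Mme have no counts in any tumour.

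The lymphomas expressed a broad B cell program. All 12 pan B cell genes were at 10 CPM or more in every tumour, and their median was 853, 1247 and 1065 CPM in tumours 1, 2 and 3. Cd74, the invariant chain of MHC class II, led the list at 8996 ± 4562 CPM, followed by Ms4a1 (CD20) at 1913 ± 882 CPM. Antigen presentation genes were also abundant. H2-Aa was at 1229 ± 296 CPM and H2-Ab1 at 1155 ± 205 CPM among 10 class II genes with a list median of 306 ± 82.2 CPM, and B2m (4127 ± 471 CPM), H2-K1 (3088 ± 663 CPM) and H2-D1 (2391 ± 694 CPM) led 9 class I genes with a median of 519 ± 130 CPM. Outside mitochondrial, ribosomal protein and immunoglobulin genes, the 10 most abundant genes were Cd74, Eef2, Hsp90ab1, B2m, Actb, Ly6e, H2-K1, Pabpc1, Serinc3 and Eef1a1, from 8996 CPM for Cd74 to 2504 ± 491 CPM for Eef1a1.

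Growth and NF-κB genes were high within the libraries. Of 26 NF-κB targets, 23 were at 10 CPM or more in every tumour (list median 142 ± 26.2 CPM), led by Tnfaip3, a feedback inhibitor of NF-κB (1130 ± 954 CPM), Ltb (548 ± 145 CPM) and Ccnd2 (442 ± 233 CPM), while Bcl2a1a had 1 count in each tumour. Proliferation genes had a median of 132 ± 52.9 CPM, with Mki67 at 837 ± 310 CPM, Top2a at 633 ± 299 CPM and Mcm6 at 310 ± 69.1 CPM. Myc itself was at 784 ± 186 CPM, and Ncl (1143 ± 79.3 CPM) and Npm1 (523 ± 106 CPM) were the other leading members of 12 Myc and ribosome biogenesis genes (median 264 ± 54.1 CPM). In the BCL2 family (median 32.1 ± 6.96 CPM), Mcl1 at 779 ± 45.5 CPM was above Bcl2, and Bak1 was at 167 ± 49.4 CPM. Bcl2a1d, a near copy of Bcl2a1a with which reads can be shared, was at 0.608 ± 0.849 CPM. Immediate early and heat shock genes had a median of 235 ± 129 CPM, led by Fosb (1434 ± 632 CPM), Jun (668 ± 513 CPM) and Junb (391 ± 169 CPM). Among checkpoint ligands (median 45.3 ± 5.34 CPM), Cd274, which encodes PD-L1, was at 310 ± 126 CPM, Cd47 at 216 ± 36.6 CPM and Cd86 at 111 ± 11.6 CPM.

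Differentiation genes were split. The germinal centre list had a median of 3.23 ± 3.44 CPM. Plxnb2 (195 ± 74.3 CPM), Mef2b (71.3 ± 74.3 CPM) and Neil1 (36.0 ± 42.4 CPM) were its most abundant members, Gcsam had no count in any tumour, and Basp1, Efnb1 and Nuggc had means of 0.647, 0.466 and 0.0376 CPM. Naive and memory B cell genes had a median of 65.4 ± 11.4 CPM, led by Klf2, a transcription factor of quiescent lymphocytes (757 ± 96.6 CPM), and Zbtb32 (382 ± 244 CPM). Plasma cell genes had a median of 39.4 ± 12.8 CPM through secretory pathway genes such as Edem1 (350 ± 74.0 CPM), Sec11c (322 ± 131 CPM) and Mzb1 (114 ± 60.3 CPM), while Sdc1 (CD138) was at 0.378 ± 0.160 CPM and Tnfrsf17 (BCMA) had 3 counts in tumour 1 and none in the other two. The p53 targets had a median of 23.4 ± 9.88 CPM, with Ccng1 at 113 ± 20.9 CPM, Mdm2 at 112 ± 45.3 CPM and Trp53inp1 at 89.4 ± 27.2 CPM, no count of Eda2r and 0, 2 and 1 counts of Phlda3. Interferon response genes had a median of 10.4 ± 5.19 CPM, with Xaf1 at 112 ± 16.4 CPM, Bst2 at 43.1 ± 16.6 CPM and Ifi44 at 0.0851 ± 0.0738 CPM.

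Among 25 lists fixed before the data were examined, 13 had a median at or above the 95th percentile of 10000 random lists of the same size drawn from 25463 genes with a count. The pan B cell, NF-κB target, proliferation, Myc, MHC class I, MHC class II, ABC classifier and immediate early lists were at percentile 100, naive and memory B cell genes at 99.9, checkpoint ligands at 99.4, housekeeping genes at 99.3, the BCL2 family at 98.7 and plasma cell genes at 97.5. The p53 targets (94.9), interferon genes (88.5), germinal centre genes (74.7) and GCB classifier genes (63.4) were below. The percentiles describe these libraries and are no test between samples. Against random lists of genes at 1 CPM or more in any library, plasma cell genes were at percentile 66.2, BCL2 family genes at 65.6, checkpoint ligands at 88.8, p53 targets at 38.6, interferon genes at 15, GCB classifier genes at 2.3 and germinal centre genes at 0.9. By RPKM with GENCODE exon lengths, an alternative chosen after seeing the data, the p53 targets were at 97.8, above the limit, and the germinal centre and GCB classifier genes at 42.1 and 19.9.

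**Figure D2:**
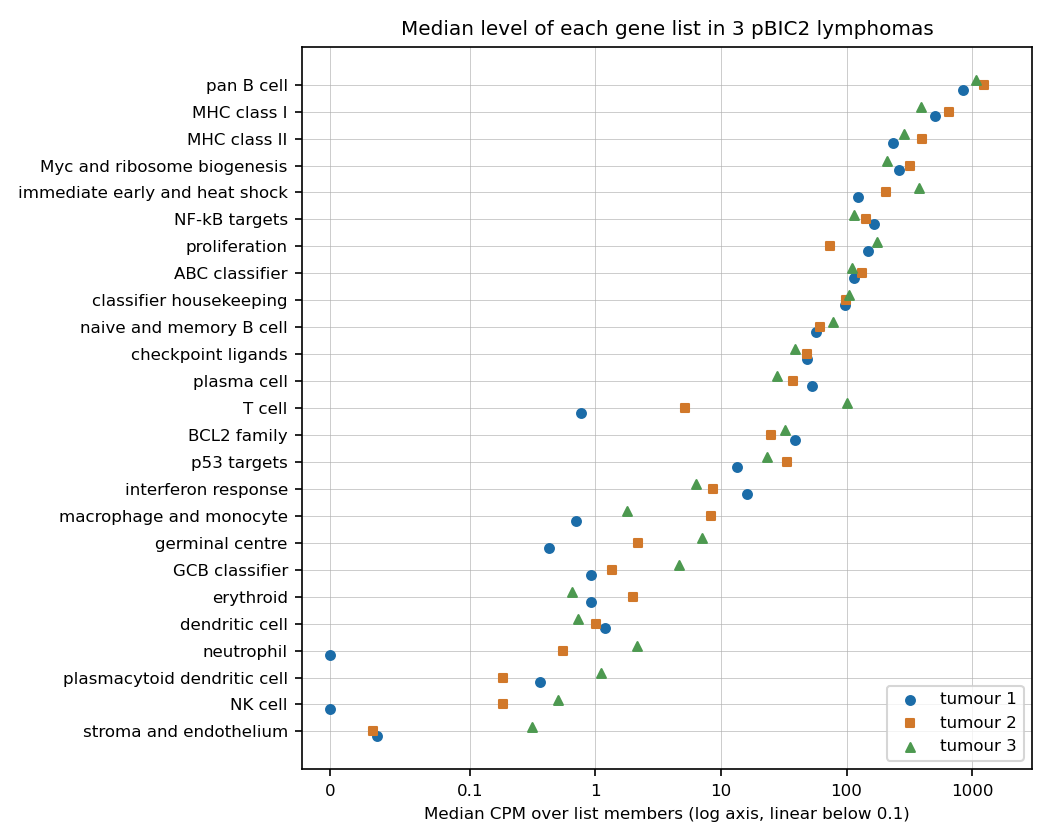
Median CPM over the members of each of 25 gene lists (log axis, linear below 0.1), with 1 symbol per tumour. The pan B cell list is highest, at 853 to 1247 CPM, and the T cell list is spread from 0.762 CPM in tumour 1 to 101 CPM in tumour 3.

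Genes that separate the ABC type from the germinal centre B cell (GCB) type of human lymphoma were compared because the labels call the model ABC-DLBCL. Of 8 ABC genes, 7 were at 10 CPM or more in every tumour: Tnfrsf13b (373 ± 126 CPM), Irf4, a transcription factor downstream of NF-κB (307 ± 79.8 CPM), Ccdc50 (300 ± 93.3 CPM), Limd1 (204 ± 31.7 CPM), Pim2 (51.2 ± 18.9 CPM), Creb3l2 (29.3 ± 13.7 CPM) and Rab29 (26.7 ± 5.59 CPM). Cyb5r2 was at 0.278 ± 0.133 CPM. Of 7 GCB genes, Itpkb (52.6 ± 32.9 CPM) and Asb13 (25.04 ± 1.65 CPM) passed 10 CPM in every tumour, and S1pr2 (3.13 ± 2.81 CPM), Mybl1 (2.004 ± 1.93 CPM) and Serpina9 (1.64 ± 2.58 CPM) were low. Maml3 had 458 counts in tumour 2 against 1 and 4 in tumours 1 and 3, and Mme (CD10) had no count. Of the 5 housekeeping genes of the classifier (list median 101 ± 4.17 CPM), R3hdm1 (179 ± 19.4 CPM), Ubxn4 (127 ± 4.47 CPM) and Trim56 (101 ± 4.17 CPM) varied little. Wdr55 (83.8, 62.9 and 46.1 CPM, SD of log2 CPM 0.432) and Isy1 (43.7, 22.7 and 36.1 CPM, SD 0.482) varied about as much as the median gene (0.439).

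The mean log2 CPM of the ABC genes exceeded that of the GCB genes by 5.23 in tumour 1, 4.47 in tumour 2 and 3.88 in tumour 3 (4.53 ± 0.68, SD, n = 3). A two-sided exact permutation of the list labels over 15 genes gave p = 0.0177, a comparison across genes, which are not independent replicates. Levels of different genes, with no normal B cells as reference, decide nothing about the lymphoma type. A sign-flip test over 3 tumours cannot give a two-sided p below 0.25. With only the genes at 1 CPM or more in all tumours the difference was 2.98 (exact permutation p = 0.0667), and without Mme and Serpina9, an alternative chosen after seeing the data, it was 3.28 (exact permutation p = 0.0738). The filter at 1 CPM removed 4 GCB genes and 1 ABC gene, so it acts on the difference itself. By RPKM with GENCODE exon lengths, also chosen after seeing the data, the difference was 5.41 (exact permutation p = 0.00668).

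Each lymphoma used a different dominant immunoglobulin rearrangement, as far as V segment counts show it. In tumour 1, Ighv11-2 (chromosome 12, 114048241 to 114048812) held 58.6% of 6305 heavy chain V counts (95% Wilson interval 57.4 to 59.8) and Igkv14-126 (chromosome 6, 67896172 to 67896642) held 88.9% of 39369 light chain V counts (88.6 to 89.2). In tumour 2, Ighv14-3 (chromosome 12, 114059845 to 114060321) held 60.2% of 6450 counts (59.0 to 61.4) and Iglv1 (chromosome 16, 19085017 to 19085500) held 76.9% of 25451 counts (76.4 to 77.4). In tumour 3, Ighv12-3 (chromosome 12, 114366521 to 114366954) held 90.5% of 12892 counts (89.98 to 90.99) and Igkv4-91 (chromosome 6, 68768555 to 68769103) held 86.9% of 20284 counts (86.4 to 87.4). Second segments above 10% were Ighv11-1 in tumour 1 (20.3%, 19.3 to 21.3), Ighv14-2 in tumour 2 (22.2%, 21.2 to 23.2) and the pseudogene Igkv4-73 in tumour 2 (10.1%, 9.77 to 10.5). Ighv2-2, named after its value was seen, ranked next in tumour 1 with 17.2% (16.3 to 18.1) and is of another family than Ighv11-2. Ighv11-1 and Ighv14-2 are close relatives of the dominant segments, so how reads were divided within these families is uncertain.

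Ighm, the IgM constant gene (chromosome 12, 113418558 to 113422730), was the most abundant heavy chain constant gene in every tumour, with 93.6% of heavy chain constant counts in tumour 1 (95% Wilson interval 93.4 to 93.8), 93.1% in tumour 2 (93.0 to 93.3) and 89.2% in tumour 3 (89.0 to 89.4). In tumours 1, 2 and 3, Ighg1 held 0.693%, 1.48% and 0.0923%, Ighg3 0.836%, 3.48% and 7.81%, and Ighd 4.40%, 0.673% and 1.18%. Igkc held 90.5% and 83.5% of light chain constant counts in tumours 1 and 3, and in tumour 2 Iglc1 held 61.9% and Igkc 24.8%. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only.

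**Figure D3:**
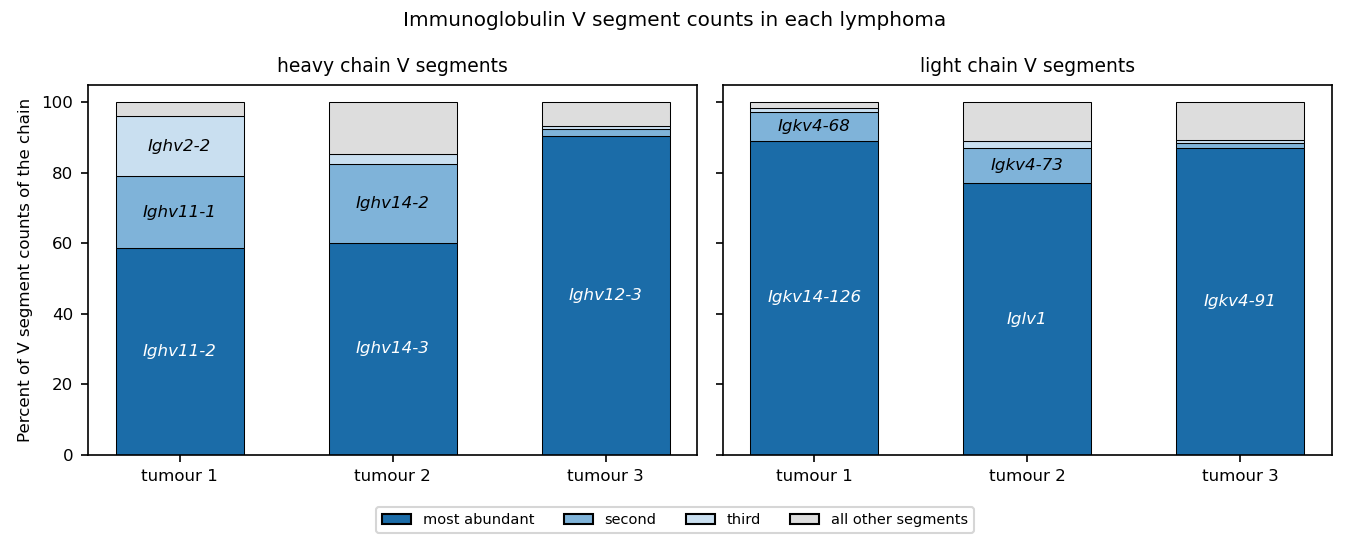
Percent of heavy chain (left) and light chain (right) V segment counts held by the most abundant segment, the next segments in rank and all other segments in each tumour. The most abundant heavy chain segment is Ighv11-2 (58.6%), Ighv14-3 (60.2%) and Ighv12-3 (90.5%) in tumours 1, 2 and 3.

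T cell genes stood out among markers of cells that the B220+GFP+ sort should remove. The median of 10 T cell genes was 0.0893% of the pan B cell median in tumour 1, 0.415% in tumour 2 and 9.50% in tumour 3 (mean 3.34%, and 0.252% without tumour 3). In tumour 3, Cd8a reached 238 CPM against 0.663 and 4.54 CPM, Thy1 189 CPM against 0.862 and 3.31 CPM, and Cd3e 57.7 CPM against 0 and 1.41 CPM, while Lck and Tcf7 were at 200 and 200.1 CPM there at 68.7 and 146 CPM in tumour 1 and at 23.5 and 11.4 CPM in tumour 2. Cd4 was highest in tumour 2, at 5.82 CPM. Of the NK cell genes, Prf1 (perforin) and Gzma were at 39.96 and 7.33 CPM in tumour 3, Klrb1c had 26 counts in tumour 1, Klrd1 and Klre1 had at most 10 and 8 counts, and Ncr1 had none.

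The other non-B lists were below 1% of the pan B cell median in every tumour. Macrophage genes were at 0.0816%, 0.669% and 0.167%, with 9 of 10 members highest in tumour 2, among them Cd68 (325 CPM), Lyz2 (32.7 CPM), Csf1r (15.6 CPM) and the complement genes C1qa, C1qb and C1qc (8.71, 10.4 and 7.97 CPM); Cd14 and Fcgr1 had at most 3 and 10 counts. Neutrophil genes were at 0%, 0.0443% and 0.201%, with 8 of 9 highest in tumour 3, among them Ngp (15.2 CPM), S100a9 (10.7 CPM), Ltf (7.27 CPM) and S100a8 (5.19 CPM), while Camp, Mpo, Elane, Retnlg and Ly6g had means under 1 CPM. Erythroid genes were at 0.109%, 0.160% and 0.0609%, led by Hbb-bs (6.36 ± 3.43 CPM), Hba-a1 (2.96 ± 1.49 CPM) and Hba-a2 (2.18 ± 0.820 CPM), with Alas2, Slc4a1 and Klf1 under 1 CPM on average. Plasmacytoid dendritic cell genes (0.0427%, 0.0148% and 0.103%; Ccr9 3.73, Cox6a2 0.937, Siglech 0.124 and Klk1 0.0597 CPM on average) and dendritic cell genes (0.140%, 0.0811% and 0.0688%; Zbtb46 2.55, Flt3 1.11, Xcr1 0.848 and Clec9a 0.0188 CPM) were low. Stroma and endothelium genes were at 0.00388%, 0.00246% and 0.0291%, although Pecam1, which B cells also express, was at 215 ± 88.2 CPM. Col1a1 had 127 counts in tumour 1, Cdh5 was at 2.19 ± 0.483 CPM, and Col1a2, Col3a1, Pdgfrb, Kdr and Dcn had means under 1 CPM. The NK cell list was at 0%, 0.0148% and 0.0476%.

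Hspa1a, an inducible heat shock gene, had 1 count in tumour 1 against 1044 and 1175, and its near copy Hspa1b 114 counts against 2958 and 2743, and Jun was at 135, 1158 and 712 CPM. Rgs13, a germinal centre regulator of G protein signalling, was at 90.1 CPM in tumour 2 against 0.0663 and 2.99 CPM, while Fas (15.2 CPM) and Bcl6 (14.5 CPM) were highest in tumour 3. Cr2 (CD21) was at 8.55, 150 and 286 CPM, Ccr6 at 0.331, 3.13 and 20.2 CPM and Fcer2a (CD23) at 3.78, 30.7 and 22.9 CPM. Derl3 was at 130, 31.0 and 6.14 CPM, Jchain at 1.39, 8.09 and 11.8 CPM, Ebi3 at 58.2, 176 and 12.9 CPM, Tnf at 55.5, 300.1 and 57.0 CPM and Tnfaip3 at 2147, 986 and 256 CPM.

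Of 20 proliferation genes, 18 were lowest in tumour 2, for example Ccna2 (175, 69.2 and 198 CPM), Top2a (643, 328 and 926 CPM) and Plk1 (53.9, 32.6 and 89.3 CPM). Of the p53 targets, Zmat3 was at 0.464, 16.7 and 28.1 CPM, Cdkn1a at 1.52, 1.90 and 9.47 CPM and Psrc1 at 1.66, 5.33 and 10.8 CPM. Xist, expressed from the inactive X chromosome, had 66596 counts in tumour 1 against 31 and 7, and the Y-linked genes Ddx3y and Eif2s3y had 1655 and 1615 counts in tumour 3, 99 and 73 in tumour 2 and 1 and 0 in tumour 1. By the median SD of log2 CPM, 10 of 22 lists were at or above the 95th percentile of 10000 random lists matched on expression, while the NK cell, plasmacytoid dendritic cell and dendritic cell lists had fewer than 3 members at a mean of 1 CPM and no value: germinal centre (99.8), plasma cell (97.7), naive and memory B cell (100), NF-κB targets (100), p53 targets (95.3), proliferation (99.9), immediate early and heat shock (100), T cell (100), macrophage (98.9) and neutrophil (99.6). Members of a list can shift together in 1 tumour, which neither the random lists nor the simulated counts copy. These percentiles therefore describe the libraries and are no test. Without tumour 2 the number of lists at or above the 95th percentile was 6. NF-κB targets, p53 targets, proliferation and macrophage genes were no longer among them. Plasma cell, naive and memory B cell and neutrophil genes were not among them without tumour 1, nor were plasma cell, p53 target and neutrophil genes without tumour 3. The p53 targets were also below the percentile with DESeq2 size factors, with total counts and with a mean of at least 5 CPM, the last of which also ended the macrophage and neutrophil calls. Other lists newly reached the percentile: GCB classifier genes without tumour 1, and ABC classifier and interferon genes without tumour 3. With a mean of at least 5 CPM, GCB classifier and interferon genes did so.

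Over 11273 genes the common biological coefficient of variation was 0.445, and Spearman correlations between tumours, taken across genes, were 0.863 to 0.891. Of 10650 genes at 5 CPM or more in any tumour, 669 (6.28%) were at least 4-fold higher or lower in 1 tumour than in both others while the others differed by less than 2-fold from each other: 95 higher and 242 lower in tumour 1, 86 higher and 52 lower in tumour 2, and 141 higher and 53 lower in tumour 3. Genes such as Xist and Cd8a, which differed by more than that between the others, are not in this count. No p-value is given, since each tumour has 1 library. The number was 388 at a log2 distance of 3, 1932 at a distance of 1, 1249 from 1 CPM and 307 from 20 CPM.

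The genes of largest distance that were higher in tumour 1 were Arhgap29 (log2 distance 7.79 to the nearer tumour), Nyx (7.11), Fam186a (6.92), Cacna1h, a calcium channel subunit (6.72; 388 CPM), and Apba1 (6.72), and those lower were Hspa1a (-8.41), the guidance receptor gene Robo1 (-8.37), Trim32 (-7.35), Neurod4 (-7.01) and Enox2 (-6.98). In tumour 2, those higher were Myh13, a muscle myosin heavy chain (10.02; 301 CPM), Epb41l4b (7.84), Stard13 (7.73), Gpr31c (7.72) and Lmcd1 (7.53), and those lower were Xlr3b (-4.94), Wipf3 (-4.80), Dnah8 (-4.47), Plekhg5 (-4.32) and Nsg2 (-4.18). In tumour 3, those higher were the T cell receptor segments Trbv13-2 (8.60) and Trbv12-2 (7.67), Kcnip3 (7.42), the hypoxia factor gene Epas1 (7.19) and Nrn1 (6.90), and those lower were Tnfsf15 (-6.28), the metallothionein genes Mt1 (-6.12) and Mt2 (-5.36), Ebf3 (-5.80) and Nlrp6 (-4.95). Many of these genes had 0 to 3 counts on the low side, where the distance depends on the prior count.

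**Figure D4:**
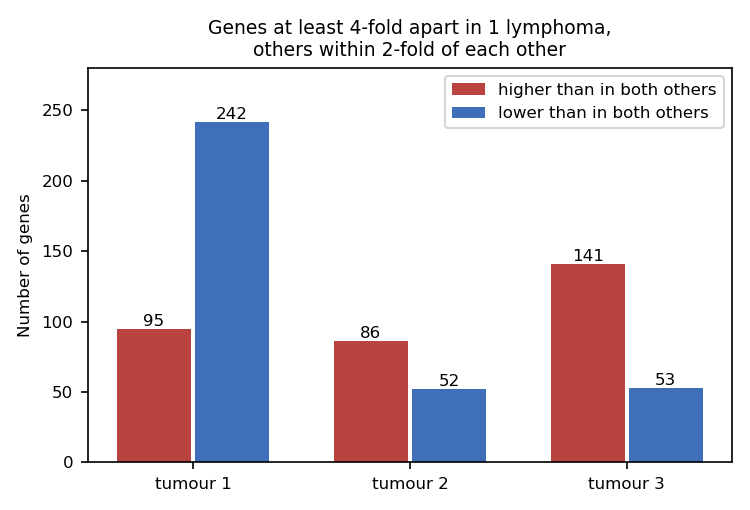
Number of genes at least 4-fold higher (red) or lower (blue) in 1 tumour than in both others, for each tumour, counting only genes whose level in the others differed by less than 2-fold. Tumour 1 has the most, with 95 higher and 242 lower genes.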

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

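Alternatives with GENCODE exon lengths, without Mme and Serpina9, and without T cell, NK cell and T cell receptor genes were chosen after seeing the data. Of 117 alternative values, 88 were kept, 29 were not and 0 reversed. A value was kept if its call stayed, or if it moved by less than 1 SD between tumours (for counts, by less than 1.5 times). For the common coefficient of variation, the SD was that of the values with each tumour left out, so these were judged against their own spread. Shares of V segments and constant genes had to stay within the Wilson interval of the main value. Leaving out 1 of 3 tumours cannot move a mean over tumours by 1 SD. For the engineered loci and the non-B lists, such values were therefore kept whatever the data, and say nothing about stability. Where that SD is wide a value can still move several-fold: without tumour 3, T cell genes were at 0.252%, NK cell genes at 0.00737%, neutrophil genes at 0.0221%, plasmacytoid dendritic cell genes at 0.0287% and stroma genes at 0.00317% of pan B cell genes (means with all tumours 3.34%, 0.0208%, 0.0818%, 0.0536% and 0.0118%), and without tumour 2 macrophage genes were at 0.124% (0.306%) and Ighg1 at 23.9 CPM (49.3 CPM). The classifier difference lost its call with only genes at 1 CPM or more in all tumours (2.98, exact permutation p = 0.0667) and without Mme and Serpina9 (3.28, exact permutation p = 0.0738), where fewer genes enter the test. With V segments of at least 10 counts only, the heavy chain shares of tumours 1, 2 and 3 were 59.9%, 62.2% and 91.8% and the light chain shares 89.2%, 77.5% and 87.6%. With constant genes in the denominator they were 3.79%, 3.33% and 8.91%, and 26.6%, 22.5% and 21.9%, which follows from the larger total. Per kb of exon the Ighm shares were 94.0%, 94.3% and 91.0%. With the mean in place of the median, NK cell, macrophage and stroma genes were at 0.210%, 1.30% and 1.76% of pan B cell genes. These means follow a single member of each list far above the others: Prf1 (13.85 CPM on average), Cd68 (170 CPM) and Pecam1 (215 CPM). By RPKM neutrophil and erythroid genes were at 0.266% and 0.445%, for which the cause was not tested. The common coefficient of variation was 0.698 with no filter on low counts, where 25463 genes enter, and 0.440 to 0.477 when each tumour was left out. Tumour-specific genes numbered 388 and 1932 at log2 distances of 3 and 1, and 1249 and 307 from 1 and 20 CPM, as the rule admits fewer or more genes. Without 1 tumour, 6 to 9 lists had high spread, with 6 without tumour 2. The planned RPKM from a length column was not run, as the tables hold no such column, and tumour-specific genes need all 3 tumours, so none was left out there. No paired analysis was possible because the labels give 1 group only. Depth limits genes near 3 counts, for which the absence of a transcript was not shown.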

Other observations

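All tests of explanations here were chosen after the patterns were seen, except the 12 further T cell genes and the further Y-linked genes, whose predictions were written before those values were looked at; the chromosome medians and their limit of 0.3 were also chosen after seeing the data.

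The median level of whole chromosomes differed between these libraries, given as values only, since each tumour has 1 library. A resampling over genes was also run, and its p-values are left out for that reason. Among genes with a mean of at least 5 CPM, the 249 genes of chromosome 18 had a median log2 difference of 0.91 in tumour 1 from the mean of the other tumours, with 90.8% of genes above, and of -0.67 in tumour 3. Chromosome 10 was at -0.76 in tumour 3 and 0.42 in tumour 1, chromosome 11 at -0.55 in tumour 1 and 0.35 in tumour 3, chromosome 2 at -0.55 in tumour 1 and chromosome 6 at 0.51 in tumour 1. Genes are not independent replicates, and each tumour is set against the others, so a shift in 1 appears with opposite sign elsewhere. Of 16 medians of at least 0.3 in size, 16 stayed there after a fit on GC content and length was removed. In 14 of these 16 (87.5%), all 4 parts of the chromosome with equal numbers of genes were shifted the same way by at least 0.15, a value taken on chromosomes picked for their shift. No explanation of these shifts is offered here. Of the 242 genes lower in tumour 1, 56 had at most 3 counts there, against 2 of 52 and 4 of 53 for the genes lower in tumours 2 and 3.

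T-lineage transcripts in tumour 3 came with a narrow T cell receptor repertoire, although a B220+GFP+ sort should remove T cells. Trbv13-2 (chromosome 6, 41121396 to 41121832) held 73.3% of 1721 Trbv counts (95% Wilson interval 71.2 to 75.4) and its neighbour Trbv12-2 held 25.5%, which argues against a mixture of many T cells. A T cell clone among the sorted cells may explain the pattern, and the test set was 12 further T cell genes, of which at least 10 were predicted to be 4-fold above both other tumours. The number was 9, among them Lat (118 CPM), Cd8b1 (63.9 CPM) and Zap70 (63.3 CPM), while Cd2 and Prkcq, among those that missed the limit, were also present in tumour 2, so the prediction was missed and this explanation stays open. Raised T cell genes would also follow from many T cells or from lymphoma cells that express them, so this number cannot single out a clone. T cell genes expressed by the lymphoma cells themselves were not tested.

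Y-linked counts were low in tumour 2. Kdm5d, Eif2s3y, Ddx3y and Uty were there at 4.78% to 7.80% of their level in tumour 3. Reads carried over from the tumour 3 library would set a floor for every gene, and 93 of 832 genes (11.2%) at least 4-fold higher in tumour 3 than in tumour 1, chosen without regard to tumour 2, had an upper Poisson limit below the lowest of these ratios (Cd8a was at 1.91%, upper limit 2.39%), which argues against it; among the 141 genes specific to tumour 3, a list chosen partly on tumour 2, it was 29.8%. Also argued against is a mixture with cells of a female that express Xist, which was at 0.0431% of its level in tumour 1. Loss of the Y chromosome from most lymphoma cells of a male may explain the pattern and predicted that at least 80% of further Y-linked genes would be 4-fold lower. The value was 50%, from 1 of 2 genes (Gm29650; the other, Gm47283, had 968 counts in tumour 1, which had at most 1 count of the other Y-linked genes), too few to decide.

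The dominant V segments of tumours 1 and 3 form pairs, Ighv11-2 with Igkv14-126 and Ighv12-3 with Igkv4-91, that are known from B-1 cells binding phosphatidylcholine. That they dominate only because reads are easily assigned to them is argued against, as the largest share any of these 4 segments held in another tumour was 1.27%. Uneven assignment could still change the size of their shares within tumours 1 and 3, which these values cannot show. A B-1 cell origin was tested with 5 B-1 genes (Cd5, Spn, Bhlhe41, Ctla4 and Plscr1; Cd5, Spn and Ctla4 are also T cell genes, so their values in tumour 3 can include its T-lineage signal) against 5 follicular B cell genes (among them Fcer2a, Cr2, Ighd and Cxcr5), the latter list changed once before the test was run, and the B-1 median was predicted to be at least 2-fold higher. It was lower, with ratios of 0.602 in tumour 1 and 0.236 in tumour 3, so the prediction was missed, and tumour 2, without such a pair, was above tumour 3 (its value is not reported here), but levels of different genes with no normal B cells as reference decide nothing about origin, and this explanation stays open. In tumours 1, 2 and 3, Cd5 was at 82.1, 33.9 and 16.01 CPM, Spn at 244, 42.9 and 255 CPM, Bhlhe41 at 557, 374 and 271 CPM, Plscr1 at 73.5, 160.4 and 67.6 CPM, Ctla4 at 4.71, 5.15 and 26.4 CPM, Cr2 at 8.55, 150 and 286 CPM, Fcer2a at 3.78, 30.7 and 22.9 CPM, Cxcr5 at 136, 290.3 and 433 CPM and Ighd at 266, 45.4 and 78.3 CPM.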
